A study of Mus musculus with 4 samples.

How the data were processed

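Single-cell RNA was measured with 10x Genomics droplets in 4 libraries of live-sorted skin tumour cells of LKPR mice, 2 control and 2 NP137. The deposited files hold UMI counts per gene and barcode, which the authors made with 10x software 3.0.2 per the file headers, against mm10 per the submitters' processing notes, which also name Seurat 3.1.5. The aligner settings and the rule that called barcodes as cells are not given in the sources used here. The files list 31053 Ensembl genes and a YFP row, which was used to find tumour cells and stayed in the sums and tests beside the mouse genes. Gene coordinates are those of GENCODE M21.

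Cells with at least 200 genes and under 20% mitochondrial UMIs were kept, 11677, 5679, 16617 and 16914 in control 1, control 2, NP137 1 and NP137 2. The highest Scrublet scores of each library, 0.8% per 1000 barcodes, were removed as doublets, 1195, 378, 2412 and 2401 cells. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1, which gave 39 clusters. A cluster was named after the marker set of highest score, with the suffix "-like". It was left unnamed where its markers were too few, its score was under a set minimum or its leading genes held more markers of another class. A cluster of few UMIs without an own marker among its leading genes was left unnamed too. Clusters with a YFP UMI in at least 50% of their cells were called YFP-positive, a class added after the values were seen. The planned mesenchymal-like class was replaced by fibroblast-like, also after seeing the data.

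UMI counts were summed per library and class, for classes with at least 50 cells in each library, and NP137 was compared with control by edgeR's quasi-likelihood test (glmQLFit robust, TMM, filterByExpr) with Benjamini-Hochberg at an adjusted p of 0.05. All p are 2-sided. CPM are UMI counts scaled to the class sum of each library with TMM factors. The 29 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 on log CPM with a prior count of 2, and beside it with an estimated correlation and with fry. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of 1 list. Shares and log2 ratios were compared by an exact permutation test over the 6 assignments of 4 libraries, whose smallest p is 0.333. For shares of cells with a UMI each cell was thinned to 2000 UMIs. Bootstrap intervals used 200 draws.

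Named genes followed a rule fixed beforehand: per comparison the 10 genes of largest log2 fold change in each direction among those that passed, with group values that do not overlap and a mean of at least 20 CPM, filled up to 6 by smallest p where fewer passed, and 5, filled up to 3, in macrophages and the classes without a comparison of their own. The 3 members of smallest p of each list that passed belong to the rule. By chance 33.3% of genes have group values that do not overlap with 2 against 2 libraries. Members of the netrin, EMT surface marker and tumour model lists were named whatever their p. A few genes that these rules or lists hold are not reported here, and other list members printed were chosen after their values were seen.

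Alternatives were DESeq2 in place of edgeR, DESeq2's size factors in edgeR, no filter on low counts, each library left out in turn, the sample number as a block, a stricter cell filter (500 genes, 10% mitochondrial UMIs), no doublets removed, Leiden resolution 2, thinning to 1000 UMIs or none, medians in place of sums, and 7 added after seeing the data.

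The tests were tested on simulated data of the same spread with 200 changed genes, each gene drawn independently of the others. The spread was edgeR's estimate per gene, so the shares recovered need not hold for the real libraries. In YFP-positive cells, with 13733 genes run, edgeR recovered 0%, 22.5% and 77.9% of genes changed by 1, 2 and 4 log2 units, and called 8 unchanged genes, while DESeq2 recovered 3.45%, 47.9% and 95.6% and called 66. The edgeR shares were 0%, 8.33% and 64.1% in all cells (16233 genes), 0%, 31.3% and 86.6% in epithelial-like cells (12790 genes), 0%, 40.3% and 93.9% in fibroblast-like cells (11834 genes) and 1.61%, 50.7% and 92.8% in macrophage or monocyte-like cells (11258 genes). For the difference between epithelial-like and fibroblast-like cells, run at a dispersion of 0.01 alone (11430 genes), they were 55.4%, 93.4% and 100%. The biological coefficient of variation was 0.447 in YFP-positive cells and 0.481 in all cells.

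Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.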

Results

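Single-cell RNA sequencing was carried out on live-sorted cells of skin tumours from LKPR mice. In these mice tamoxifen deletes p53 and labels the recombined cells with yellow fluorescent protein (YFP), all starting from cells that express Lgr5. NP137 is an antibody that blocks netrin-1, a secreted guidance protein that also acts as a survival and state signal in tumours. It was injected at 10 mg/kg every 2 days from 4 weeks after tamoxifen. Tamoxifen was given to all mice as 4 injections of 2.5 mg from postnatal day 28. Tumours were detected at 7 to 9 weeks, so the NP137 injections may have begun before tumours could be seen. No sample was taken before treatment. A shift of existing tumour cells therefore cannot be told apart from a difference in the tumours that formed. The series asks whether blocking netrin-1 shifts tumour cells away from the epithelial-mesenchymal transition (EMT), in which epithelial cells lose adhesion and keratin genes and gain fibroblast-like ones. There were 2 control and 2 NP137 libraries. The labels do not say that the libraries are separate animals, so each p below measures only the spread between these 4 samples.

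The files held 12792 and 8328 barcodes for control 1 and control 2, and 18146 and 17745 for NP137 1 and NP137 2, although 10000 cells were loaded per channel. Total UMIs per library were 88076950 and 73685280 for the controls and 69517664 and 149021188 for NP137. After filters and doublet removal 10482, 5301, 14205 and 14513 cells were used, 44501 in all, with medians of 4567.5, 5957, 2355 and 5154 UMIs per cell. Every live cell had been sorted, so immune and stromal cells were read beside tumour cells. The files of control 1 and NP137 1 carry the same date, and those of control 2 and NP137 2 carry later, different dates. Sex-linked genes were read as a check on the samples. Xist alone was seen in 64.3% of the cells of control 1 and 68.0% of NP137 2, with Y-linked genes alone in 0.02% and 0% of cells. Control 2 had Y-linked UMIs alone in 51.2% of cells and Xist alone in 0.30%. NP137 1 held both kinds, Xist alone in 27.7% and Y-linked genes alone in 16.7% of cells.

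Cells of the recombined lineage, called tumour cells here, were compared first. Recombined cells carry the YFP transcript, and 6 of the 39 clusters had a YFP UMI in at least 50% of their cells, a limit chosen after the values were seen. The 6 ranged from 76.2% to 96.1%, and the next cluster stood at 32.0%. These YFP-positive clusters also carried Cdkn2a, a transcript that rises when p53 is lost. With each cell thinned to 2000 UMIs it was found in 83.3% and 75% of control cells and 64.3% and 38.4% of NP137 cells, against 22.7%, 4.91%, 6.49% and 0.92% of the macrophages of control 1, control 2, NP137 1 and NP137 2. They gave 4457 and 1137 cells in the control libraries and 3097 and 929 in the NP137 libraries.

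YFP-positive cells of control tumours carried mesenchymal genes, and most of those of NP137 tumours carried keratinocyte genes. In control 1 and control 2 they made collagens, fibronectin and Pdgfra, with little Epcam and few adhesion genes. In NP137 1 and NP137 2 they made Epcam, basal keratins, desmosome and tight-junction genes and the transcription factors that hold the epithelial state. By the fixed marker sets 7.02% and 1.85% of the control YFP-positive cells fell in epithelial-like clusters, against 78.9% and 99.8% of those of NP137 (exact 2-sided permutation test, p = 0.333). With 2 against 2 libraries that test cannot give a p under 0.333. Different clusters filled the class in each library. In control 1 82.4% of its cells lay in a cluster led by H19 and Mme, and in control 2 94.8% lay in one led by Mgp and Clu. In NP137 1 72.3% lay in a cluster led by Wfdc2 and Pitx1, and in NP137 2 89.3% lay in one with Tchh and Il24 among its leading genes. Neither of these control clusters took a class name. Fewer than 3 markers of the set of highest score were detected in them, and that set was not the mesenchymal-like one. A further 18.76% of NP137 1 lay in an unnamed cluster led by Fxyd2 and Rbp4, with Epcam in 16.3% and Vim in 99.55% of its cells.

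The epithelial state list rose in NP137 YFP-positive cells (camera adjusted p = 2.3e-21, adjusted p = 0.86 with an estimated correlation). Adjusted over the list alone, 43 of its 46 tested members rose and 0 fell by edgeR's quasi-likelihood test, and adjusted over all genes 0 passed and 46 did not. The median log2 fold change was 3.38. Epcam (ENSMUSG00000045394, chr17:87635979-87651129, GRCm38/mm10) stood at 62.1 and 21.6 CPM in control libraries and 950 and 944 CPM in NP137 libraries, a log2 fold change of 4.50 with a standard error of 0.60. Krt14 (ENSMUSG00000045545) went from 1250 and 285 CPM to 11070 and 14700 CPM. Rab25, a trafficking gene of epithelia, had a log2 fold change of 4.77 with a standard error of 0.53, and the desmosome gene Dsp stood at 40.4 and 31.8 against 277 and 481 CPM. The epithelial splicing factor Esrp1, the transcription factors Grhl2, Ovol1 and Ovol2 and the claudins Cldn4 and Cldn7 were also among the 43. Krt8, Krt15 and Cldn1 were not. Krt8 stood at 389 and 187 CPM in controls and 263 and 225 CPM under NP137.

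The mesenchymal state list fell in the same cells (camera adjusted p = 5.2e-17, adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone, 35 of 44 members fell and 1 rose, and 8 did not pass, with a median log2 fold change of -3.31. Fn1 (ENSMUSG00000026193, chr1:71585520-71653200) stood at 2214 and 1577 CPM in control libraries and 42.1 and 53.4 CPM in NP137 libraries. Bgn stood at 1015 and 845 against 51.7 and 40.6 CPM, and Pdgfra had a log2 fold change of -4.92 with a standard error of 0.34. The EMT transcription factor Zeb1 stood at 74.3 and 57.3 against 8.55 and 1.14 CPM, and Snai1 at 45.3 and 39.7 against 3.38 and 1.52 CPM. Col1a1, Col3a1, Cdh2, Loxl2 and Zeb2 were among the 35 as well. Snai2 was the member that rose, from 13.5 and 23.2 to 32.9 and 73.9 CPM. Vim fell short of the list threshold, at 5220 and 4111 against 1537 and 180 CPM, and Twist1 separated the 2 NP137 libraries, at 205 and 204 against 135 and 1.45 CPM.

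**Figure D1:**
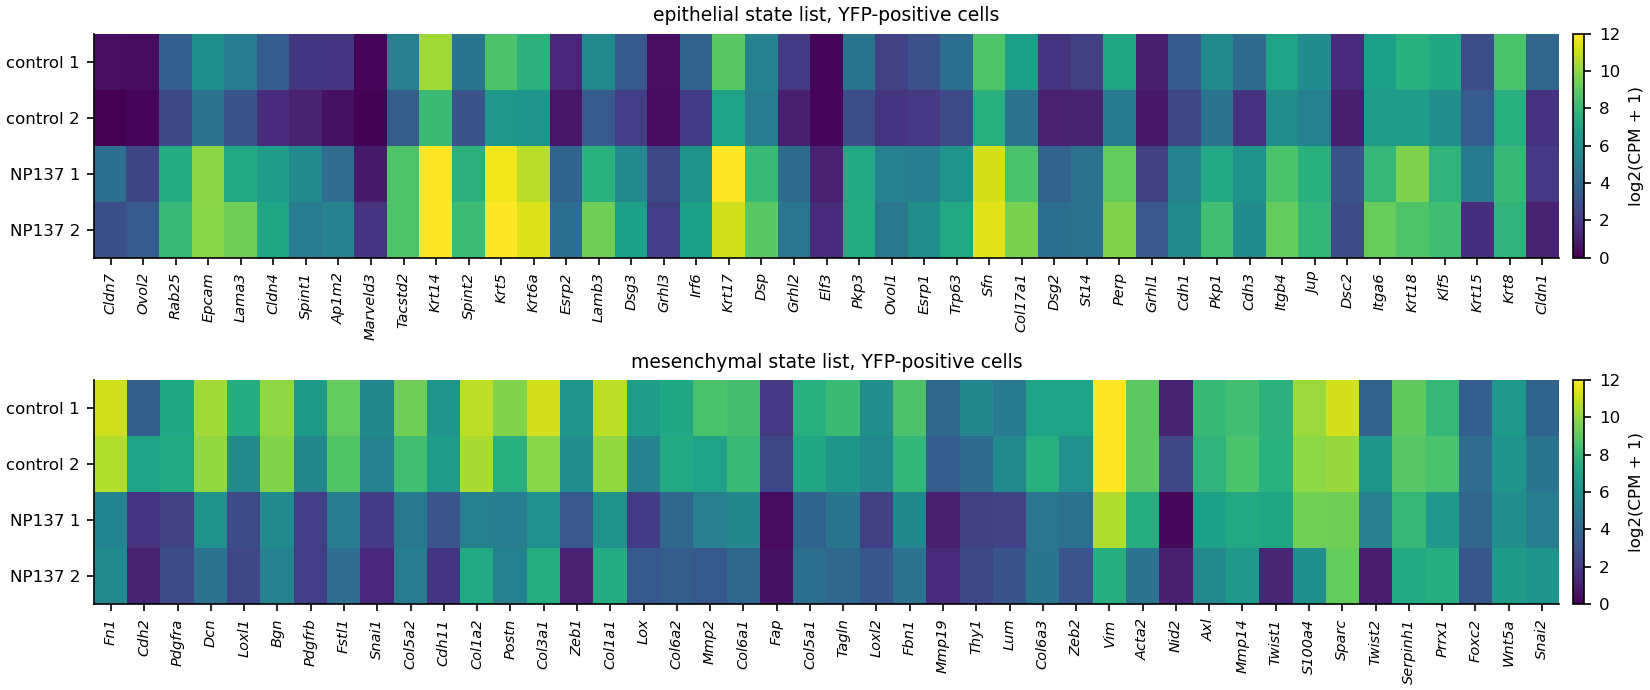
Levels of tested members of the epithelial state and mesenchymal state lists in YFP-positive cells, as log2(CPM + 1), 1 strip per library and 1 column per gene, ordered by fold change. Epcam stands at 62.1 and 21.6 CPM in the control strips and 950 and 944 CPM in the NP137 strips, and Fn1 at 2214 and 1577 against 42.1 and 53.4 CPM.

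The summed CPM of the mesenchymal list over that of the epithelial list, as a log2 ratio, was 2.53 and 3.59 in control YFP-positive cells and -2.67 and -3.96 in NP137 ones (exact 2-sided permutation test, p = 0.333). Within the pair of libraries of the same date the ratio was 2.53 in control 1 and -2.67 in NP137 1. Cells with sex-linked UMIs allowed the same reading within 1 library. In NP137 1 the YFP-positive cells with Xist alone gave -3.33 and those with Y-linked UMIs alone -2.41, so that both kinds of YFP-positive cell lay on the epithelial side. Control 1 cells with Xist alone gave 1.75, and control 2 cells with Y-linked UMIs alone gave 3.67.

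Per cell the same contrast was seen at equal depth. After each cell was thinned to 2000 UMIs, Epcam was found in 4.89% and 3.65% of control YFP-positive cells and in 62.6% and 72.0% of NP137 ones. Macrophage or monocyte-like cells, which should lack Epcam, gave 2.09%, 5.83%, 15.8% and 2.93% in control 1, control 2, NP137 1 and NP137 2, so control 1 stood at 2.34 times this background, control 2 below it, and NP137 1 and NP137 2 at 3.97 and 24.5 times. Krt14 was found in 34.7% and 30.1% of control YFP-positive cells, below its macrophage background of 38.9% and 45.7%, and in 98.6% and 99.7% of NP137 cells against 82.6% and 26.3%. Vim was found in 97% and 97% of control and 59% and 23% of NP137 cells. Vcam1 went from 38.5% and 21.6% to 1.52% and 0.11%. Zeb1 went from 14.5% and 10.8% to 1.66% and to 0 of 896 cells, which allows up to 0.335%, at or near the 1.03% and 0.745% of macrophages. A share of cells carried both an epithelial UMI and Vim, 38.7% and 33.5% in controls and 57.7% and 22.9% under NP137. In macrophages, which make Vim themselves, that share was 51.0%, 55.5%, 76.5% and 34.1%, above that of the YFP-positive cells of the same library. Without thinning Epcam was found in 9.98%, 20.1%, 74.0% and 94.5% of YFP-positive cells. Their median depths were 8861, 27461, 8717 and 18661 UMIs, against 3904, 9542, 2120 and 6085 UMIs in macrophages. Cells under 2000 UMIs were left out, 242, 13, 204 and 33 per library.

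**Figure D2:**
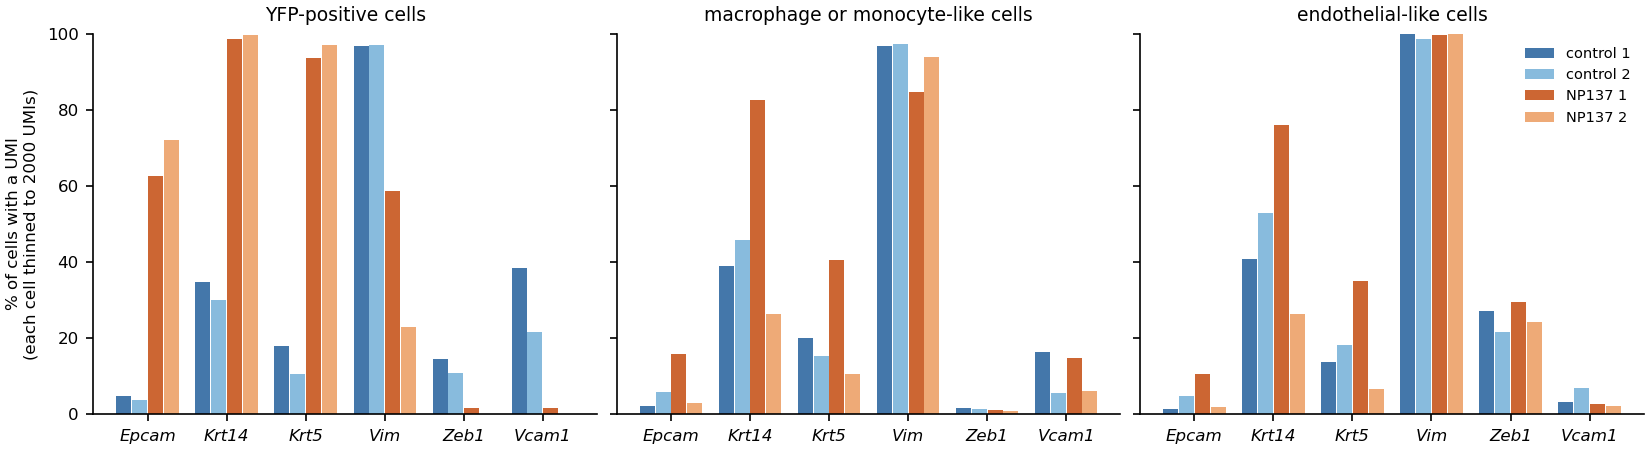
Percent of cells with at least 1 UMI of each gene after thinning to 2000 UMIs, in YFP-positive cells and in 2 classes that serve as background, with 1 bar per library. Epcam in YFP-positive cells stands at 4.89% and 3.65% in control libraries and 62.6% and 72.0% in NP137 libraries.

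The ligand that the antibody binds was itself low in NP137 tumour cells. Ntn1 (ENSMUSG00000020902, chr11:68209364-68400823) stood at 68.4 and 40.3 CPM in control YFP-positive cells and at 1.41 and 0.19 CPM in NP137 ones, a log2 fold change of -5.99 with a standard error of 0.93 (edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 0.078, and 4.75e-12 by DESeq2). Its receptor gene Unc5b (ENSMUSG00000020099) stood at 53.7 and 69.7 against 20.5 and 7.01 CPM, and the co-receptor Rgmb at 34.0 and 50.2 against 15.4 and 16.6 CPM. Neo1 overlapped between the groups, at 49.8 and 20.3 against 23.3 and 40.0 CPM. Adora2b went the other way, from 4.38 and 1.80 to 10.6 and 26.5 CPM. The netrin list fell as a whole (camera adjusted p = 0.045, adjusted p = 0.84 with an estimated correlation), with 4 of 10 members lower and 1 higher adjusted over the list alone. That call was lost without control 1 (camera adjusted p = 0.12) and without NP137 2 (camera adjusted p = 0.067). Of the fixed EMT surface markers, Vcam1 stood at 281 and 119 against 9.11 and 1.52 CPM, Itgb3 at 12.5 and 22.9 against 2.30 and 0.76 CPM and Itgav at 124 and 101 against 42.4 and 55.1 CPM. Of the tumour model genes, Trp53 stood at 8.90 and 20.1 against 12.3 and 4.68 CPM, Cdkn2a at 1253 and 917 against 709 and 351 CPM and Lgr5 at 1.98 and 1.63 against 0.52 and 1.01 CPM.

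**Figure D3:**
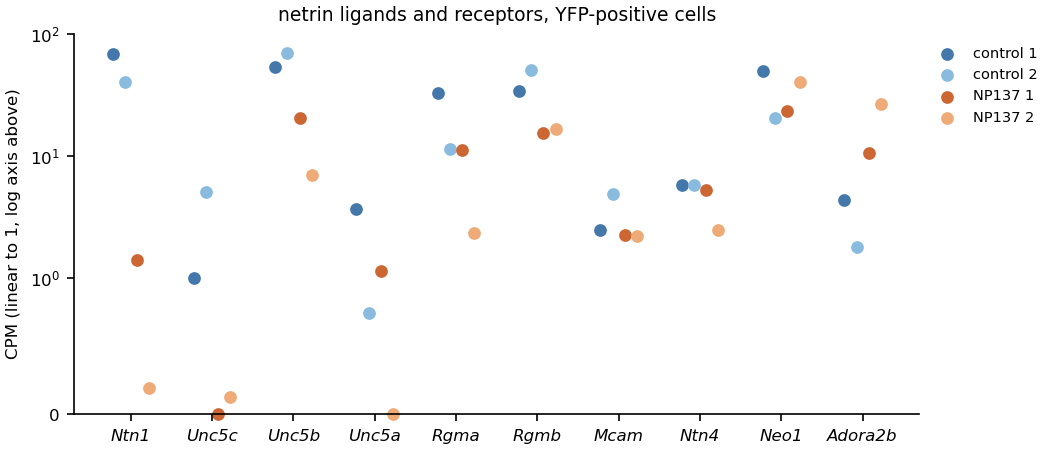
CPM of the tested netrin ligands and receptors in YFP-positive cells, 1 point per library, on an axis that is linear to 1 and logarithmic above. Ntn1 stands at 68.4 and 40.3 CPM in control libraries and 1.41 and 0.19 CPM in NP137 libraries.

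Further gene lists moved between the groups in YFP-positive cells. The hypoxia, ribosomal protein, S phase, type I interferon and TGF-beta lists moved the same way in other classes too, as given below. Whether any of them follows the state of the YFP-positive cells was not tested. Keratinocyte differentiation genes rose, 11 of 17 adjusted over the list alone and 0 lower (camera adjusted p = 2.2e-05, adjusted p = 0.59 with an estimated correlation), among them Sprr1b at 6.67 and 5.40 against 67.3 and 159 CPM and Krtdap at 83.2 and 30.5 against 1381 and 865 CPM. Hypoxia and glycolysis genes rose, 7 of 22 with 0 lower (camera adjusted p = 2.2e-05, adjusted p = 0.86 with an estimated correlation), among them Ldha at 631 and 600 against 2017 and 2545 CPM. S phase genes rose, 3 of 22 with 0 lower (camera adjusted p = 0.0034, adjusted p = 0.86 with an estimated correlation), such as Tyms at 45.9 and 69.0 against 170 and 162 CPM. Ribosomal protein genes rose, 11 of 20 with 0 lower (camera adjusted p = 9.0e-06, adjusted p = 0.86 with an estimated correlation). Type I interferon response genes fell, 11 of 23 with 0 higher (camera adjusted p = 9.0e-06, adjusted p = 0.86 with an estimated correlation), such as Ifit1 at 4.80 and 19.5 against 0.41 and 0.82 CPM. The TGF-beta list fell, 3 of 20 with 0 higher (camera adjusted p = 0.041, adjusted p = 0.86 with an estimated correlation), with Tgfb2 at 49.7 and 56.9 against 6.95 and 4.61 CPM and Ltbp1 at 135 and 85.8 against 15.1 and 20.8 CPM. Targets of the YAP coactivator fell on balance (camera adjusted p = 0.046, adjusted p = 0.84 with an estimated correlation), 9 of 12 lower, such as Ctgf at 143 and 96.9 against 19.7 and 11.9 CPM, and 3 higher. All of these counts are adjusted over the list alone. Without control 1 the calls of the TGF-beta, YAP and S phase lists were lost (camera adjusted p = 0.34, 0.13 and 0.29), and without NP137 1 those of the TGF-beta and YAP lists (0.20 and 0.12).

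Over all 14044 genes tested in YFP-positive cells 1 fell and 0 rose at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg, while 3317 had an unadjusted p under 0.05 and DESeq2 called 2232, 990 higher and 1242 lower. The gene that passed was the transcription factor Nr2f1 (ENSMUSG00000069171, chr13:78188973-78199757), at 86.9 and 88.9 CPM in control and 0.59 and 0.57 CPM in NP137 cells (log2 fold change -7.23, standard error 0.32, adjusted p = 0.038 by edgeR's quasi-likelihood test). The others of smallest p that were lower and did not pass were Fn1, Bgn, Pdgfra, Myh10 and Cthrc1. Those higher were Ly6d, Krt6b, Shroom3, Fabp5, Krt16 and Tmem238, with log2 fold changes from 2.29 to 4.34. Their edgeR adjusted p was 0.067 to 0.070 in both directions. The count rested on which libraries were read: it was 425 without control 1, 288 without NP137 1, and 0 without control 2 or without NP137 2. It was also 0 with no doublets removed, with each library clustered on its own, with cells chosen by a YFP and a Cdkn2a UMI and with the sample number as a block (smallest adjusted p = 0.088, 0.060, 0.052 and 0.12). On simulated libraries of the same spread edgeR recovered 0% of genes changed by 1 log2 unit, 22.5% by 2 and 77.9% by 4.

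Summed over all cells, whatever their type, epithelial, hypoxia, antigen-presentation and T cell lists rose in NP137 libraries at camera's preset correlation alone. The sums mix states with the cell types that each library held. The epithelial state list rose (camera adjusted p = 3.3e-06, adjusted p = 0.87 with an estimated correlation), with 43 of 48 members above 0 and a median log2 fold change of 0.98, although Epcam overlapped between the groups, at 57.2 and 200 against 650 and 176 CPM. The hypoxia and glycolysis, MHC class I and MHC class II lists rose (camera adjusted p = 1.4e-06, 0.040 and 0.036, each 0.87 with an estimated correlation). Lists of cytotoxic and of exhausted or regulatory T cells rose (camera adjusted p = 0.030 and 0.0024, both 0.87 with an estimated correlation). Higher genes of smallest p were Rbp4 at 5.25 and 2.51 against 82.5 and 63.2 CPM, Sncg, Il24, Ifitm1, Mcpt8 and Lamb3. Lower ones were Aqp1 at 352 and 277 against 34.8 and 19.0 CPM, Sema3a, Dkk2, Pla2g7 and Lrig1. Of 16610 genes 0 passed by edgeR's quasi-likelihood test, with 1083 at an unadjusted p under 0.05 and 295 called by DESeq2, and 4 passed without NP137 1.

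In epithelial-like cells, YFP-positive and others together, the cell cycle lists had the smallest camera p. The G2 and M phase list rose (camera adjusted p = 2.9e-06, adjusted p = 0.68 with an estimated correlation), with 22 of 22 members above 0 and a median log2 fold change of 0.97, and so did the S phase list (camera adjusted p = 2.9e-06, adjusted p = 0.68 with an estimated correlation). Hypoxia and glycolysis genes rose too, with 19 of 22 above 0 (camera adjusted p = 9.7e-04, adjusted p = 0.68 with an estimated correlation). Hair follicle stem cell genes, YAP targets and MHC class I genes fell (camera adjusted p = 0.0084, 0.020 and 0.0065, each 0.68 with an estimated correlation). Lists that follow RNA quality and handling moved too: mitochondrially encoded genes fell with 13 of 13 below 0 and dissociation genes with 14 of 16 (camera adjusted p = 0.0084 and 0.0097, both 0.68 with an estimated correlation). Of the epithelial-like cells 53.3% and 1.89% in the controls and 47.2% and 92.5% under NP137 were YFP-positive, so the groups mixed YFP-positive and other cells in different shares. Of 13149 genes 0 passed by edgeR's quasi-likelihood test, with 987 at an unadjusted p under 0.05 and 18 called by DESeq2. Higher genes of smallest p were Tubb3 at 30.0 and 19.4 against 77.1 and 125 CPM, Ass1, Mthfd2, Pop5, Sult2b1 and Pclaf. Lower ones were Susd6 at 64.8 and 115 against 25.9 and 24.3 CPM, Tenm2, Ltbp4, Zbtb20, Tcf4 and Acsl4.

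Epithelial-like cells outside the YFP-positive clusters numbered 274, 1089, 2732 and 75 in control 1, control 2, NP137 1 and NP137 2. They were not clear of recombined cells: a YFP UMI was found in 26.6%, 17.1%, 29.0% and 42.7% of them against 17.6%, 10.6%, 9.28% and 3.02% of macrophages, and after thinning Cdkn2a in 32.6%, 9.99%, 13.0% and 10.0% against 22.7%, 4.91%, 6.49% and 0.92%. The epithelial state list rose with 33 of 47 members above 0 and a median of 0.40, and keratinocyte differentiation genes rose with 15 of 19 above 0 (each camera adjusted p = 0.0011, 0.72 with an estimated correlation). The class was made up differently in each library: the differentiated cluster led by Cst6 and Krt79 held 12.04%, 23.42%, 22.77% and 57.33% of it and the basal one led by Krt15 76.28%, 66.85%, 52.96% and 22.67%. The mesenchymal state list, with 19 of 41 members above 0 and a median of -0.07, did not pass (camera adjusted p = 0.93), and neither did the type I interferon list, with a median of 0.35 (camera adjusted p = 0.14). Hypoxia genes and the G2 and M phase list rose (both camera adjusted p = 4.0e-06, 0.72 with an estimated correlation), and basement membrane genes fell, with 16 of 19 below 0 (camera adjusted p = 0.0027, adjusted p = 0.72 with an estimated correlation). Stmn2, at 44.8 and 43.1 against 7.20 and 7.75 CPM, had the smallest p of the lower genes, followed by Susd6 and Egr3. Stmn2 was also a leading gene of the cluster at 32.0% YFP, and its log2 fold change in fibroblast-like cells was -2.44. RNA from other cells was not excluded as its source. S100a8, Ovol1 and Ccdc71l had the smallest p of the higher genes, S100a8 at 209 and 241 against 733 and 1667 CPM. S100a8 is a neutrophil gene, found in 20.8%, 22.1%, 27.2% and 62.7% of these cells and in 19.5%, 21.5%, 22.3% and 40.4% of macrophages, so its rise may come from outside these cells. Among 11418 genes 0 passed by edgeR's quasi-likelihood test, with 722 at an unadjusted p under 0.05 and 25 called by DESeq2. The count was 20 without control 1, 408 without NP137 1 and 10 without NP137 2.

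Cell cycle lists rose in fibroblasts of NP137 libraries at camera's preset correlation alone, and the G2 and M phase list did so in other classes too. The planned mesenchymal-like class was read as fibroblast-like, resting fibroblasts included, since the clusters nearest its markers also carried resting markers. The G2 and M phase list rose with 22 of 22 members above 0 and a median log2 fold change of 1.49 (camera adjusted p = 6.2e-18, adjusted p = 0.67 with an estimated correlation), and the S phase list rose with 21 of 22 above 0 (camera adjusted p = 2.1e-08, adjusted p = 0.67 with an estimated correlation). In the same cells mitochondrially encoded genes fell with 13 of 13 below 0, dissociation genes fell with 14 of 16 below 0 and ribosomal protein genes rose with 20 of 20 above 0 (camera adjusted p = 0.019, 0.035 and 1.0e-05, and 0.83, 0.73 and 0.67 with an estimated correlation). Markers of tumour-associated macrophages fell there too, with 12 of 14 below 0 (camera adjusted p = 0.011, adjusted p = 0.67 with an estimated correlation). For these macrophage markers RNA from other cells was not excluded as the source. Cks2 stood at 66.3 and 42.9 against 125 and 135 CPM, and Prc1 at 10.7 and 10.4 against 27.4 and 40.8 CPM. The mesenchymal state list fell slightly, with a median of -0.18 (camera adjusted p = 0.036, adjusted p = 0.67 with an estimated correlation), and the netrin list fell with 9 of 10 below 0 (camera adjusted p = 0.0055, adjusted p = 0.67 with an estimated correlation). Lower genes of smallest p were Sparcl1 at 106 and 124 against 35.0 and 23.4 CPM, Fbln7, Ltbp4, Thbs4, Fibin and Wnt9a, and higher ones beside the cycle genes Prc1, Cks2 and Cenpf were Gpc3, Nsg1 and Bzw2. By edgeR's quasi-likelihood test 0 of 12114 genes passed, with 360 at an unadjusted p under 0.05 and 8 called by DESeq2, and 2 passed without NP137 1. The clusters differed by library: 69.3% of the fibroblast-like cells of control 2 lay in the cluster led by Coch and Apod, 60.9% of those of NP137 1 in the cluster led by Mmp13 and 41.7% of those of NP137 2 in the cluster led by Tagln and Actg2. In control 1 the Coch and Apod cluster held the largest part, 31.5%.

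Epithelial-like and fibroblast-like cells together, the compartment planned for the EMT reading before YFP was known to be in the files, did not separate the groups. Fibroblast-like cells made up 60.3% and 18.4% of it in controls and 32.2% and 75.4% under NP137 (exact 2-sided permutation test, p = 0.667). The log2 ratio of the mesenchymal to the epithelial list was 1.82 and -0.94 against -0.83 and 2.63. Thinned Epcam was found in 22.5% and 57.7% against 55.3% and 18.0% of these cells, and Vim in 82.4% and 37.9% against 53.7% and 81.0%. Most control tumour cells lay outside this compartment: 39.5% and 21.1% of all control cells were YFP-positive without an epithelial-like or fibroblast-like name, against 4.6% and 0.01% under NP137. For genes whose NP137 effect differed between epithelial-like and fibroblast-like cells, 0 of 13883 passed by edgeR's quasi-likelihood test, with 415 at an unadjusted p under 0.05 and 6 called by DESeq2.

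Antigen-presentation and cell cycle lists rose in macrophages and monocytes of NP137 libraries at camera's preset correlation alone. The MHC class II and MHC class I lists rose (camera adjusted p = 0.014 and 0.0017, both 0.63 with an estimated correlation), with 6 of 7 and 15 of 19 members above 0. So did the exhausted or regulatory T cell list, with 7 of 9 above 0, and ribosomal protein genes, with 20 of 20 (camera adjusted p = 6.9e-04 and 0.0053, and 0.63 and 0.67 with an estimated correlation). The G2 and M phase list rose with 22 of 22 above 0 (camera adjusted p = 4.3e-08, adjusted p = 0.63 with an estimated correlation). TGF-beta genes fell with 14 of 19 below 0 (camera adjusted p = 0.0011, adjusted p = 0.63 with an estimated correlation), beside the mesenchymal state list with 28 of 42 and dissociation genes with 13 of 16 below 0 (camera adjusted p = 0.0093 and 0.011, and 0.67 and 0.63 with an estimated correlation). For the T cell and mesenchymal lists RNA from other cells was not excluded as a source. Dnase1l3 stood at 8.87 and 12.7 against 38.7 and 43.1 CPM and Cx3cr1 at 260 and 196 against 110 and 116 CPM, with S100a9 and Ltb also higher and Ank and Mef2a lower. Ank was a leading gene of the control tumour cells and S100a9 is a neutrophil gene, and both moved alike in other classes. By edgeR's quasi-likelihood test 0 of 11512 genes passed, with 389 at an unadjusted p under 0.05 and 10 called by DESeq2, and 4 passed without NP137 1. The cluster led by Fcrls and F13a1 held 53.9% of the macrophages of control 1, while the one led by Ccl6 and Folr2 held 44.4% in control 2 and 55.4% in NP137 2. The cluster led by Mmp12 had the MHC class II genes H2-Ab1, Cd74, H2-Aa and H2-Eb1 next. It held 29.1% and 13.6% of the macrophages of the controls and 63.7% and 15.1% of those of NP137 1 and NP137 2, so NP137 2 lay within the range of the controls.

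In neutrophils hypoxia genes rose, with 20 of 21 members above 0 (camera adjusted p = 2.7e-06, adjusted p = 0.83 with an estimated correlation), and mitochondrially encoded genes fell, with 13 of 13 below 0 and a median of -1.28 (camera adjusted p = 1.3e-06, adjusted p = 0.83 with an estimated correlation). Slco2a1, Ank and Lrig1 were the lower genes of smallest p, Ank at 134 and 135 against 20.2 and 5.07 CPM, and Gpx2, Mmp13 and Klk8 the higher. Gpx2 and Klk8 were leading genes of the tumour cluster that held most YFP-positive cells of NP137 2, and Mmp13 led a fibroblast cluster, so RNA from other cells was not excluded as their source. In T and NK cells the G2 and M phase list rose with 16 of 16 above 0 and a median of 1.30 (camera adjusted p = 1.2e-07, adjusted p = 0.76 with an estimated correlation), while the mesenchymal state list fell with 27 of 31 below 0 and dissociation genes with 12 of 16 (camera adjusted p = 2.5e-05 and 0.0080, and 0.76 and 0.66 with an estimated correlation). Col1a1 was found in 33.33%, 54.55%, 12.79% and 69.43% of the T or NK cell-like cells of control 1, control 2, NP137 1 and NP137 2. RNA from other cells was therefore not excluded as the source of the mesenchymal list there. Gzmf stood at 655 and 179 against 2.00 and 0 CPM in T and NK cells. Lrp1 and Cp, another leading gene of the control tumour cells, were also lower there, and G0s2, Gpx2 and Frat2 were higher. By edgeR's quasi-likelihood test 0 genes passed in either class, with 354 and 521 at an unadjusted p under 0.05 and 10 and 13 called by DESeq2. In neutrophils the count was 77 without control 1, 83 without NP137 1 and 6 without NP137 2, and in T and NK cells 478 without NP137 1 and 26 without NP137 2. The neutrophil cluster led by Retnlg held 82.6% and 98.5% of the class in the libraries of the shared date, control 1 and NP137 1, against 14.8% and 2.80% in control 2 and NP137 2.

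In vessel cells of NP137 libraries the type I interferon list fell at camera's preset correlation alone. In endothelial cells the type I interferon list fell with 22 of 22 members below 0 and a median of -0.98 (camera adjusted p = 1.4e-04, adjusted p = 0.73 with an estimated correlation), and in pericytes or smooth muscle cells it fell with 17 of 18 below 0 (camera adjusted p = 7.9e-06, adjusted p = 0.74 with an estimated correlation). Hypoxia genes rose and dissociation genes fell in endothelial cells (camera adjusted p = 1.2e-05 and 0.0056, both 0.73 with an estimated correlation), and the G2 and M phase list rose in pericytes with 22 of 22 above 0 (camera adjusted p = 7.0e-08, adjusted p = 0.74 with an estimated correlation). Vwf stood at 409 and 405 against 179 and 157 CPM in endothelial cells, where Nin and Mfhas1 were also lower and Ifitm1 was higher. In pericytes Ank, Tgfbi and Ifih1 were lower and Mmp13 was higher. S100a8 and S100a9 were among the higher genes of smallest p in both classes, S100a9 at 43.8 and 42.7 against 216 and 222 CPM in endothelial cells. In either class 0 genes passed by edgeR's quasi-likelihood test, with 778 and 338 at an unadjusted p under 0.05 and 2 and 7 called by DESeq2. In endothelial cells the count was 124 without control 1 and 3 without control 2, and in pericytes 1 without control 1, 39 without NP137 1 and 8 without NP137 2.

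**Figure D4:**
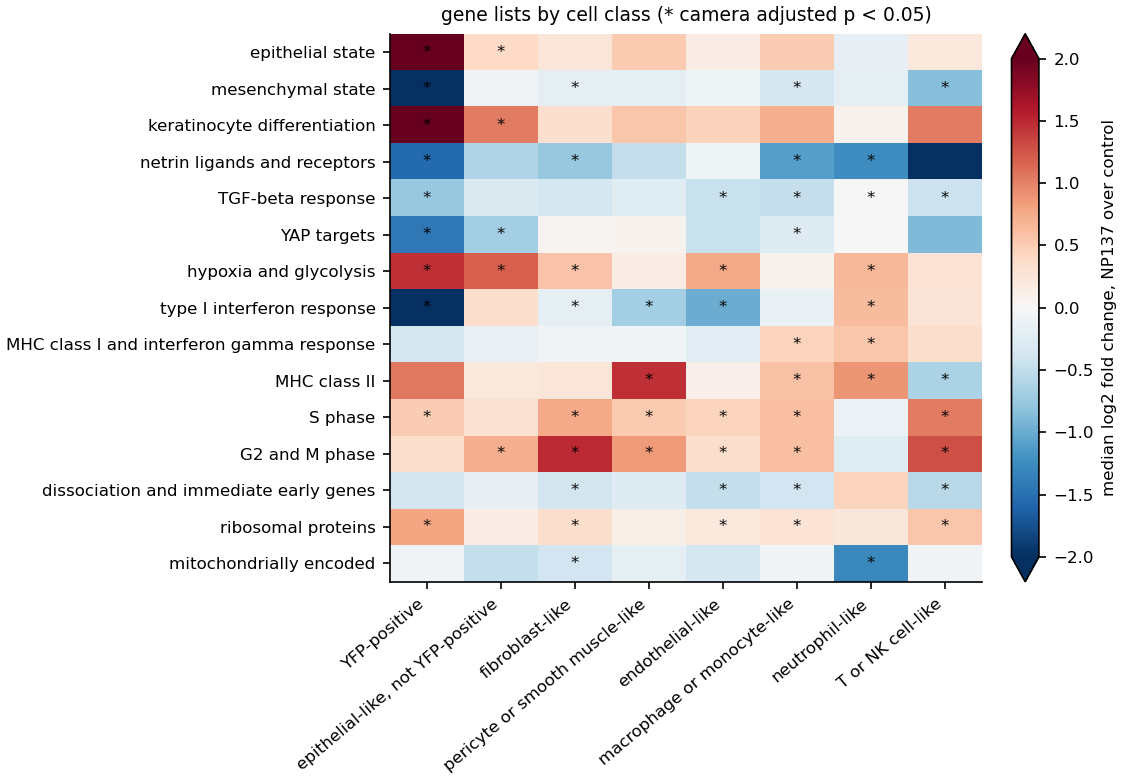
Median log2 fold change, NP137 over control, of 15 fixed gene lists in 8 cell classes, with an asterisk where the camera adjusted p is under 0.05. The epithelial state list stands at 3.38 and the mesenchymal state list at -3.31 in YFP-positive cells, and the G2 and M phase list at 1.49 in fibroblast-like cells.

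Some cell types differed in share between the groups, and others overlapped. Neutrophil-like cells made up 7.72% and 3.57% of control cells and 16.7% and 20.2% of NP137 cells, fibroblast-like cells 8.49% and 4.74% against 17.3% and 21.1%, and T or NK cell-like cells 2.12% and 1.87% against 3.08% and 5.57%. Each of these 3 differences gave p = 0.333 in the exact 2-sided permutation test, the smallest it allows. That separation was lost for neutrophil-like cells with the stricter cell filter, at 11.6% and 4.16% against 6.94% and 23.2%, and for fibroblast-like cells with each library clustered on its own, at 16.7% and 4.94% against 13.8% and 20.7% (exact permutation test, both p = 0.667). Pericyte or smooth muscle-like cells made up 2.12% and 2.23% against 3.18% and 3.31%. YFP-positive cells made up 42.5% and 21.4% of control cells and 21.8% and 6.40% of NP137 cells (exact permutation test, p = 0.667). They separated the groups at Leiden resolution 2, at 42.5% and 25.4% against 22.9% and 6.64%, and with the stricter cell filter, at 40.8% and 28.8% against 25.0% and 7.04% (exact permutation test, both p = 0.333). Macrophage or monocyte-like cells (23.1% and 6.24% against 8.65% and 16.4%), epithelial-like cells (5.60% and 20.9% against 36.4% and 6.90%) and endothelial-like cells (2.77% and 5.43% against 3.32% and 1.73%) overlapped between the groups. Without control 1 the macrophage difference changed sign to 6.30 percentage points, and without NP137 1 that of epithelial-like cells changed sign to -6.37. Clusters without a name and below the YFP limit made up 5.97% and 32.3% of control and 3.15% and 14.8% of NP137 cells. Among them a cluster of few UMIs led by Ccl3, nearest to the neutrophil-like markers and with S100a8 in 87.2% to 93.8% of its cells, held 2.39%, 0.66%, 0.18% and 10.5% of control 1, control 2, NP137 1 and NP137 2. In control 2 the largest of them, a low-UMI cluster led by AY036118 and Mgp, held 31.0% of the library. The cluster at 32.0% YFP, just under the limit, held 3.40%, 0.57%, 0.46% and 0.10% of the 4 libraries.

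**Figure D5:**
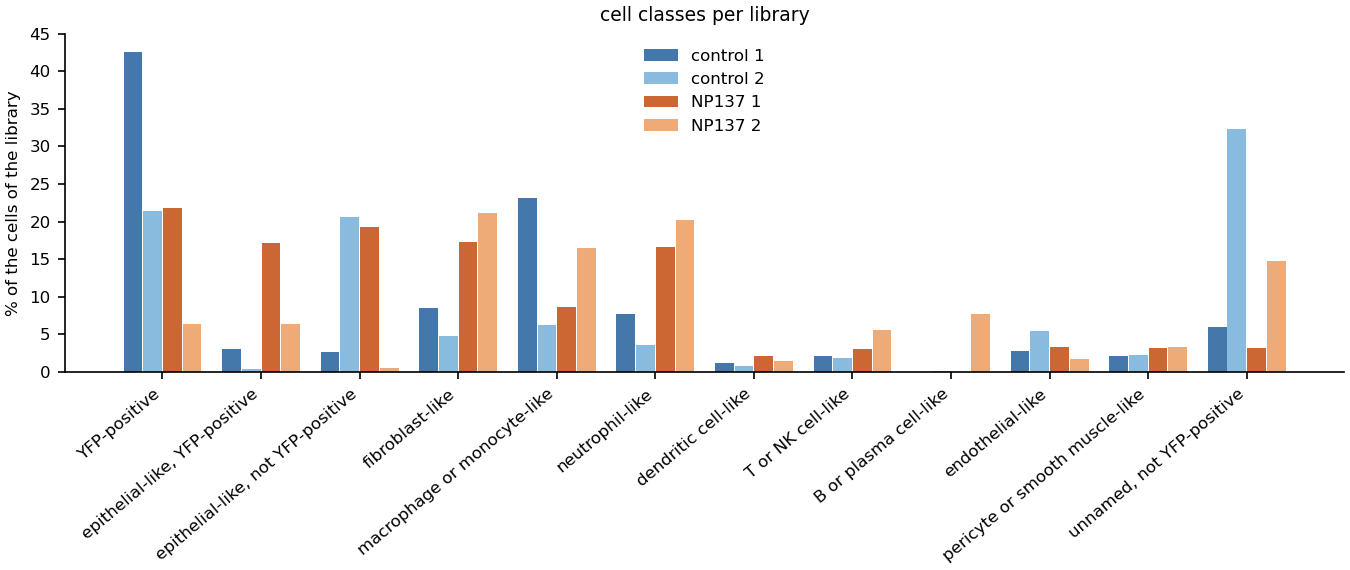
Percent of the cells of each library in each class, 1 bar per library. Neutrophil-like cells stand at 7.72% and 3.57% in control libraries and 16.7% and 20.2% in NP137 libraries.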

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

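The tests of normal keratinocytes, of 1 tumour per library and of free RNA from YFP-positive cells had their predictions written before the test was run, and the other tests below were chosen after the result was seen. B or plasma cell-like cells were set apart because 1 library held nearly all of them, 7.64% of the cells of NP137 2, too few elsewhere for a comparison. A cluster without a class name, led by Gzme, Gzmd and Mcpt8, was set apart as a signal outside the compared classes. It was nearest to the mesenchymal-like markers, had Lrrc15, Inhba, Mmp13 and Serpine2 among its leading genes and Col1a1 in 100% of its cells in both NP137 libraries, and stood at 2.41% of the cells of NP137 1 and 4.20% of NP137 2, above both control libraries.

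The epithelial state of NP137 tumour cells against the mesenchymal state of control tumour cells was weighed first. Free keratinocyte RNA and free YFP RNA on normal keratinocytes did not account for it, since the Epcam share was at least 3.97 times its background in each NP137 library and the Cdkn2a share at least 3.84 times that of the other epithelial-like cells. Neither did depth, with an Epcam share 12.8 times higher after thinning, or sex, with a log2 ratio at least 5.08 apart within 1 sex-linked kind. YFP marks recombined cells, and whether all YFP-positive cells were tumour cells was not tested. A test of swapped barcodes, at 0.639% of the epithelial-like YFP-positive cells of control 1, decided nothing, since swaps make libraries more alike. In NP137 1 the Xist and the Y-linked YFP-positive cells both lay on the epithelial side, the larger log2 ratio being -2.41. That would speak against a single epithelial tumour only if both kinds were tumour cells, which was not tested. Xist alone was found in 15.43% and Y-linked UMIs alone in 37.23% of its YFP-positive cells. In its other epithelial-like cells these shares were 44.99% and 10.03%. A single epithelial tumour in NP137 1 was therefore not excluded. The log2 ratio differed by -6.37 between the group means, with standard deviations of 0.75 and 0.91 within the groups. An effect of NP137 is a hypothesis that cannot be told apart from differences between tumours apart from the treatment, since each group holds 2 libraries whose animals are not stated. The exact permutation test (p = 0.333) decided nothing here, as 2 against 2 libraries cannot give less.

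Genes of the control tumour cells, such as Ank and Cp, were lower in immune cells of NP137 libraries. Free RNA of YFP-positive cells could account for this in immune cells: of the 100 genes of smallest p that fell in YFP-positive cells, 69 were tested in neutrophil-like, 43 in T or NK cell-like and 81 in macrophage or monocyte-like cells, with median log2 fold changes of -0.46, -0.93 and -0.46 (nearest to 0, -0.456). Their levels in neutrophil-like cells of control 1 followed those in its YFP-positive cells (Spearman rho 0.742, and 0.594 in T or NK cell-like and 0.601 in macrophage or monocyte-like cells). In control 2 rho was 0.625, 0.319 and 0.506. Outside the immune classes the medians were nearer to 0, at -0.31 in endothelial-like and -0.24 in pericyte or smooth muscle-like cells. In control 1 and control 2 rho was 0.287 and 0.232 in endothelial-like cells. In pericyte or smooth muscle-like cells it was 0.622 and 0.515, so rho did not set the immune classes apart. No biological explanation was tested for it.

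Library NP137 1 held cells with Xist and cells with Y-linked UMIs. Free RNA or swapped barcodes did not account for the mixture, since cells with both were 0.225 times as frequent as chance gives, 165 against 733.5. Cells of at least 2 animals could account for it, since each of the 12 classes of 50 cells or more held both kinds, the lower at 5.67% or more of its cells. Some of these classes share cells, as YFP-positive and epithelial-like cells were counted whole and in parts. In control 2 Xist alone was seen in 0.30% of all cells but in 3.93% of its 331 macrophages. A further 2.11% of these held both kinds, 0.515 times as many as chance gives, and the source of their Xist UMIs was not tested. Whether other libraries pool animals of 1 sex stays open.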

How the results depend on the processing

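Each choice was changed 1 at a time, and every difference below is NP137 minus control. In YFP-positive cells the log2 ratio of the mesenchymal to the epithelial list stayed negative under every alternative, with a difference from -7.55 to -4.82, and the difference of the Epcam share stayed between 45.7 and 69.2 percentage points. Of the values of named genes without 1 library, 428 kept their direction and side of the threshold, 72 came to pass, 2 no longer passed and 2 turned. Under other alternatives 862 kept both, 177 came to pass and 4 no longer passed. Where 1 library was left out its group held 1 library, assumed to vary like the other group. The alternatives that clustered each library on its own, made clusters without the state and marker genes, or took cells with a YFP and a Cdkn2a UMI were chosen after seeing the data. Epithelial-like cells outside the YFP-positive clusters gave no value with the stricter cell filter, at Leiden resolution 2 or with each library clustered on its own, and the difference between epithelial-like and fibroblast-like cells was not run with each library clustered on its own. Where no cause is named below, the cause was not tested. Depth limited the shares: at 2000 UMIs per cell Itgb3 was found in under 5% of the YFP-positive cells of each library, and 0 of 896 cells allows up to 0.335%.

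DESeq2 called 295 genes in all cells, 2232 in YFP-positive, 18 in epithelial-like, 25 in epithelial-like cells outside the YFP-positive clusters, 8 in fibroblast-like, 10 in macrophage or monocyte-like, 10 in neutrophil-like, 13 in T or NK cell-like, 2 in endothelial-like and 7 in pericyte or smooth muscle-like cells, and 6 for the difference between epithelial-like and fibroblast-like cells. On simulated libraries of the YFP-positive spread it called 66 unchanged genes where edgeR called 8. Without the filter on low counts edgeR called 1217 genes in YFP-positive cells, 160 in epithelial-like cells outside the YFP-positive clusters, 252 in fibroblast-like, 87 in macrophage or monocyte-like, 58 in neutrophil-like, 241 in T or NK cell-like, 128 in endothelial-like and 57 in pericyte or smooth muscle-like cells, and 4 for the difference between the 2 classes. In YFP-positive cells the stricter cell filter gave 157 genes, and 0 were left with no doublets removed, with each library clustered on its own, or with cells chosen by a YFP and a Cdkn2a UMI. In neutrophil-like cells 4 passed with no doublets removed.

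Leaving out 1 library moved the count of genes from 0 to 4 in all cells, 0 to 425 in YFP-positive cells, 0 to 408 in epithelial-like cells outside the YFP-positive clusters, 0 to 2 in fibroblast-like, 0 to 4 in macrophage or monocyte-like, 0 to 83 in neutrophil-like, 0 to 478 in T or NK cell-like, 0 to 124 in endothelial-like and 0 to 39 in pericyte or smooth muscle-like cells. The count of gene lists moved from 4 to 12 in all cells, 9 to 17 in macrophage or monocyte-like, 8 to 15 in neutrophil-like, 6 to 13 in T or NK cell-like and 3 to 11 in pericyte or smooth muscle-like cells.

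With the correlation estimated, camera passed 0 lists in every class, and so did fry. The epithelial state list in YFP-positive cells then had an adjusted p of 0.86 with camera's estimated correlation and 0.16 with fry, and the mesenchymal state list 0.59 and 0.073. In the simulated libraries a list moved by 1 log2 unit in YFP-positive cells was also missed with an estimated correlation (camera adjusted p = 0.86), while camera at the preset correlation called it (adjusted p = 1.7e-05) together with 1 list that had not been moved. These libraries drew each gene independently, so members of a list were not correlated. They therefore cannot tell whether the preset or the estimated correlation is the better one for the real lists. With no doublets removed camera passed 7 lists in macrophage or monocyte-like, 13 in epithelial-like cells outside the YFP-positive clusters, 13 in neutrophil-like, 5 in T or NK cell-like, 11 in endothelial-like and 8 in pericyte or smooth muscle-like cells.

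The sample number of the titles was also used as a replicate block, although the labels share only a number and no pairing is stated. The correlation of the sample 1 minus sample 2 differences between the groups was -0.167 in all cells, 0.026 in YFP-positive, -0.193 in epithelial-like, -0.022 in fibroblast-like and 0.193 in macrophage or monocyte-like cells. With the block 0 genes passed in YFP-positive cells and 7 lists passed in pericyte or smooth muscle-like cells. Within the block of sample 1 the difference of endothelial-like cells turned to 0.549 percentage points. In epithelial-like and fibroblast-like cells together that block turned the fibroblast-like fraction to -28.1, Epcam to 32.8, Cdh1 to 1.36, Krt14 to 39.1, Vim to -28.7, Vcam1 to -6.95, Cdh2 to -0.638 and cells with both an epithelial and a Vim UMI to 6.05 points, and the log2 ratio to -2.64. Within the block of sample 2 epithelial-like cells turned to -14.0 points, macrophage or monocyte-like cells to 10.2, YFP-positive cells with both UMIs to -10.7, and in the 2 classes together Zeb1 to 2.47 and Itgb3 to 1.27.

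Leaving out 1 library moved the share of epithelial-like cells from -6.37 to 23.2 points, of macrophage or monocyte-like cells from -10.5 to 6.30 and of YFP-positive cells with both UMIs from -13.2 to 21.6. In the 2 classes together it moved the fibroblast-like fraction from -7.15 to 36.0, Epcam from -22.1 to 15.2, Krt14 from -35.2 to 20.6, Vim from -15.0 to 29.4, Zeb1 from -3.43 to 0.672, Vcam1 from -3.28 to 8.94, Itgb3 from -1.46 to 0.864, Cdh2 from -0.764 to 1.09, both UMIs from -14.2 to 11.9 and the log2 ratio from -1.27 to 2.19. Neo1 in YFP-positive cells had log2 fold changes from -0.66 to 0.65 without 1 library, 0.65 without control 1 and 0.13 without NP137 1. At Leiden resolution 2 epithelial-like cells turned to -5.45 points and Cdh2 to -0.119. With no doublets removed Epcam turned to 0.736, Itgb3 to 0.151, Cdh2 to -0.578 and the log2 ratio to -0.032. With each library clustered on its own Epcam turned to 2.05, Vcam1 to -3.94 and Cdh2 to -0.276, and without the state and marker genes the log2 ratio turned to -0.16. The stricter cell filter turned Cdh2 to -0.0228 and both UMIs to 0.477, and thinning to 1000 UMIs turned Cdh2 to -0.100. With no thinning YFP-positive cells with both UMIs turned to -16.4, and in the 2 classes together Vim turned to -5.75, Zeb1 to 2.10 and Itgb3 to 0.321.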

Other observations

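The T and NK cells of the libraries differed in kind, as clusters chosen after their values were seen. Cells led by Cd3g, Trdc and Il17a, genes of gamma delta T cells, made up 61.3% of the class in control 1, 46.5% in control 2, 82.7% in NP137 1 and 5.69% in NP137 2. Cells led by Ccl5 and Ms4a4b, with granzyme genes, made up 37.8%, 18.2%, 17.4% and 94.2%. A further cluster led by Cd3g and Trdc, without Il17a among its leading genes, made up 0.9%, 35.35%, 0% and 0.12%. Dendritic cell-like cells made up 1.19% and 0.83% of control cells and 2.06% and 1.38% of NP137 cells.

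Neutrophil-like cells carried Cdkn2a UMIs, a gene of the tumour cells, in 40.9%, 15.3%, 6.84% and 1.74% of cells in control 1, control 2, NP137 1 and NP137 2. Between any 2 libraries 24 to 86 barcodes were shared, 64 of them between control 1 and NP137 1. Control 2 lost 31.8% of its barcodes to the mitochondrial limit, against 8.43%, 8.37% and 4.09% in control 1, NP137 1 and NP137 2.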
